A study of Mus musculus with 2 samples.

How the data were processed

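CTCF ChIA-PET was measured in embryonic stem cells of the 129S1CastF1 strain from a male mouse embryo, in 2 libraries that the labels number as biological replicates 1 and 2 of a single group. Per the labels, chromatin was fragmented by sonication and fragments of 350 to 600 bp were kept, following an in situ ChIA-PET protocol. For each replicate there were 3 deposited files on the mm10 assembly. The deposited loop files give whole-number PET counts for pairs of anchors, from 3 upward, and per the deposited README they were derived from the filtered alignments of that replicate. The deposited peak files are in narrowPeak format and hold an integer score up to 1000, a fold enrichment ratio over the background of the peak caller, and the -log10 of its p and q; the deposited peak names state that no input library was used. The deposited signal files give the number of unique reads covering each base, a raw signal coverage that was not scaled for depth, and per the deposited README peaks and signal came from the unfiltered alignments. The aligner, the callers and their versions are not given in the sources used here. The units were checked on the values: loop counts and coverage were whole numbers, and no loop joined different chromosomes.

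Loops and peaks on chromosomes 1 to 19, X and Y were analysed. The mitochondrial loop of each replicate was left out of the comparisons and its PETs were left out of the PET totals. The depth behind the values was 1988682 and 386233 nuclear loop PETs and a signal sum of 20260089917 and 8712925388 read bases. PETs without molecular identifiers are not independent molecules, so intervals cover counting error only. The tests, the gene lists, the loci, the rule for named genes and most alternatives were chosen before the data were examined; 12 alternatives were added after seeing the data and are named as such.

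A loop was counted as found in the other replicate when 1 loop there overlapped both anchors by at least 1 bp, and a peak when any peak overlapped it by at least 1 bp. For tests on single loops, shared loops were pairs that were each other's match with the most PETs. Chance was estimated by moving loops or peaks along the chromosome by 100 seeded random offsets of 200 kb to 5 Mb. Span was the distance between anchor centres. A promoter was a window of 2.5 kb on each side of a gene start of GENCODE release M21, taken per gene symbol, and a gene counted as having a shared loop when both members of the pair overlapped its window with the same anchor. The start was the upstream end of the whole gene entry, and starts of shorter transcripts were not used. Each gene list was tested against all other protein-coding genes with a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 15 lists, at 0.05. Noncoding members such as H19 were kept in their lists.

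The CTCF motif was built from the textbook consensus on 1000 peaks of odd-numbered chromosomes, of which 845 held a match, giving a weight matrix of 20 positions. It was called at the score reached by 5% of control windows of the same width 5 kb from the peaks. The orientation of a loop was read from the best motif in the peaks of each anchor, and the convergent share was tested against 25% with an exact binomial test, two-sided, with Wilson 95% intervals. PET counts of shared loops were tested against the ratio of their totals with an exact binomial test per loop, two-sided, with Benjamini-Hochberg adjustment at 0.05. Signal was averaged over each chromosome and divided by the median of the 19 autosomes. It was correlated between replicates on the log2 scale over 10 kb bins after adding 0.1 of the median. Blocks without signal were stretches of at least 10 kb that were empty in the signal tracks of both replicates. Those made almost wholly of N in the assembly were left out, and those partly of N were kept. There is 1 group, so no paired analysis and no test between groups was possible.

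The named genes followed a rule. For each list, up to 4 members were named with the highest share of the loop PETs at a shared loop, taking the lower of the 2 replicates, and members without a loop where these were 4 or fewer. The other named items were the 10 shared loops ranked highest by the same measure, the 10 protein-coding genes with the most shared loops at their promoters, all 25 loci, and the 5 loops with the largest ratio in each direction among those past the threshold of the ratio test. Members of the olfactory receptor, vomeronasal receptor, ribosomal protein and protocadherin lists were taken by name pattern. A few results that the rule would name are left out because they are withheld for evaluation.

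The alternatives changed the PET minimum to 5 or 10, the overlap to 50% of both intervals, the anchor width by 5 kb or 1 kb, the promoter window to 1 or 5 kb, the motif score to that of 1% of controls, the motif to the consensus with up to 2 mismatches, the bin width to 1 or 100 kb and the locus window to 500 kb, thinned replicate 1, used the same number of peaks or the higher-scoring part of them, or left out a replicate. Those added later restricted loops by span or to regions with signal, genes to those with a peak, and signal bins by GC content.

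The steps were tested on simulated data. The matching found 1500 of 1500 planted shared loops among 5000 and called no others, and 2503 of 2503 planted convergent pairs among 4000 were read as such. With no true change, the ratio test called 0 of 28170 loops. With 200 loops of any depth changed, it found 0 at 2-fold and 5.5% at 4-fold. With 200 changed loops of at least 50 PETs it found 6% at 2-fold and 79.5% at 4-fold, and called 2 and 3 unchanged loops. These counts were drawn from the binomial model of the test, without the PET minimum in each replicate or the pairing by anchors. They therefore cannot show how many calls in the real data were false. Of 100 random lists of 40 genes, 5 had an unadjusted p under 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9 were used.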

Results

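The data were a CTCF ChIA-PET experiment in male mouse embryonic stem cells of the 129S1CastF1 strain. CTCF is the zinc finger protein that marks domain boundaries and loop ends in vertebrate genomes, and ChIA-PET joins DNA ends held together by a chosen protein and reads the joined pairs as paired-end tags (PETs). There was 1 group with 2 biological replicates, which were separate biosamples of the same donor, so the only comparison was between replicates and no test between conditions was possible. Replicate 1 listed 396143 loops on the nuclear chromosomes with 1988682 PETs, and replicate 2 listed 92770 loops with 386233 PETs. Loops with only 3 PETs, the lowest count present, made up 51.2% of replicate 1 and 56.0% of replicate 2. Replicate 1 had 278196 peaks and a mean coverage of 7.43 reads per base, and replicate 2 had 210832 peaks and a mean coverage of 3.20. Both anchors of every loop lay on the same chromosome. In what follows, pairs of values give replicate 1 and then replicate 2, and positions are 1-based mm10 coordinates of the anchors in replicate 1.

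The strongest loop found in both replicates spanned the imprinted Kcnq1 domain. It joined an intron of the potassium channel gene Kcnq1 (chromosome 7, 143147380 to 143160973) to a region at the promoters of Cdkn1c, a maternally expressed inhibitor of cyclin-dependent kinases, and of the solute carrier gene Slc22a18 (143459281 to 143479005). It spanned 315 kb, had 679 and 219 PETs and its CTCF motifs pointed toward each other in both replicates. A second loop from the same intron reached the promoter of Phlda2, an imprinted growth regulator of the placenta, over 351 kb with 62 and 28 PETs. Within 250 kb of Kcnq1 there were 481 and 111 loops, of which 59 pairs were shared.

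**Figure D1:**
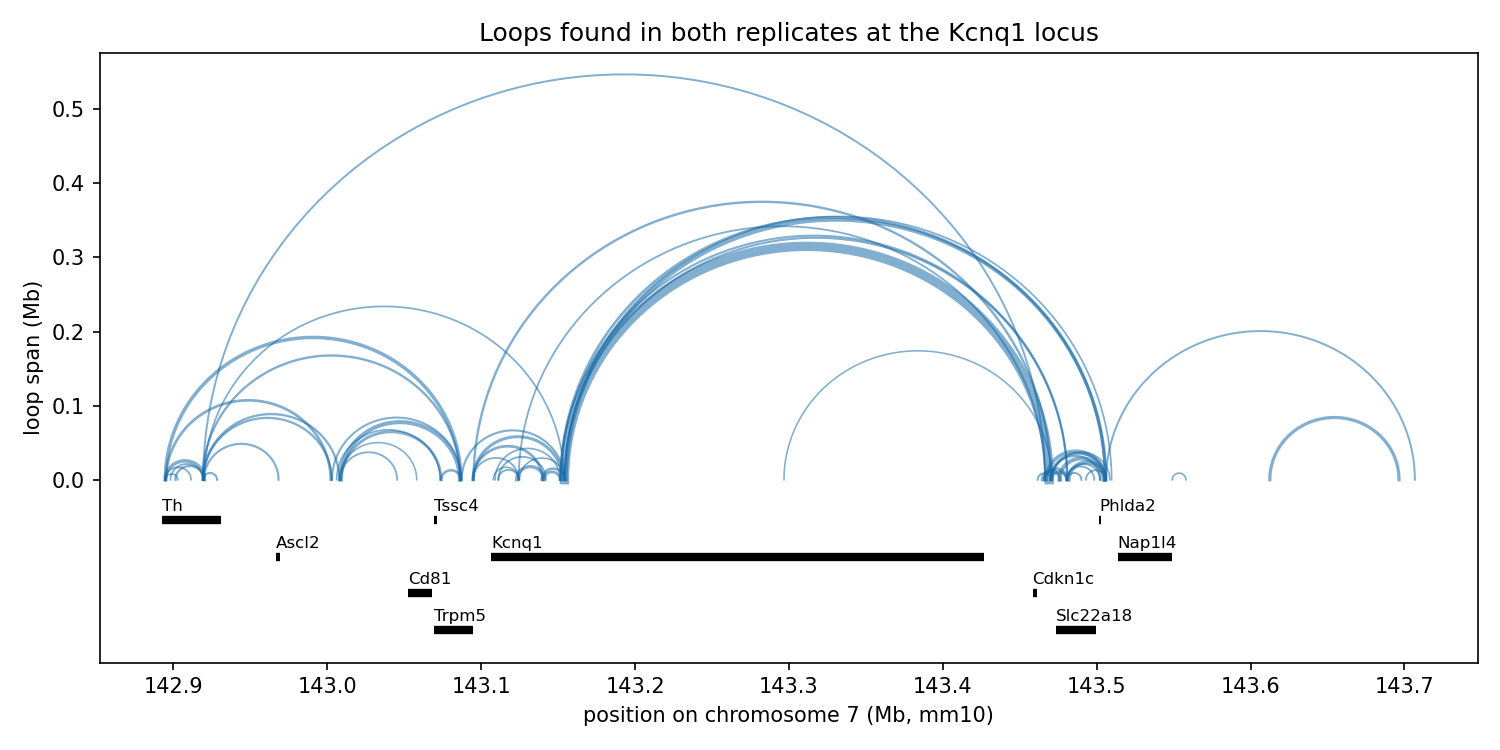
Loops found in both replicates within 250 kb of Kcnq1, drawn as arcs over position on chromosome 7 (Mb) with the height giving the span (Mb), wider lines for more PETs, and genes as bars below. The widest arc is the 315 kb loop between the Kcnq1 intron and the region of Cdkn1c and Slc22a18.

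The other strongest shared loops mostly lay at promoters and were short. The median anchor of the 10 strongest was 9635.5 bp in replicate 1, against 980 bp over all its loops. How far this width raised their PETs and their overlap with promoters was not tested. The promoter of Nes, which encodes the neural progenitor filament protein nestin, was joined to a site downstream over 12.8 kb (chromosome 3, 87968187 to 87988986) with 445 and 129 PETs and convergent motifs in both replicates. A 118 kb loop ended at the promoter of Ago2, the Argonaute protein that cleaves target RNA (chromosome 15, 73064261 to 73188364), with 303 and 102 PETs and convergent motifs. Loops at Cd82, a tetraspanin gene, spanned 53.2 kb with 519 and 76 PETs, and at Pebp1, a Raf kinase inhibitor gene, 15.1 kb with 322 and 61 PETs. On chromosome 19, the shared promoter region of Mrpl43, Twnk and Lzts2 was joined to an intron of Pdzd7 over 19.9 kb with 523 and 93 PETs. The loop between Ybx2, a germ cell gene, and the glucose transporter gene Slc2a4 spanned 12.97 kb with 378 and 94 PETs, and a loop on chromosome 13 (23399093 to 23414186) with no promoter and no motif at an anchor had 288 and 103 PETs. The loop between Stac3, Ndufa4l2, Shmt2 and Nxph4 on chromosome 10 had 811 and 70 PETs, and its anchors overlapped each other in replicate 1. Of the 10 strongest shared loops, 4 had convergent motifs in both replicates, and 5 were still paired when 50% of both anchors had to overlap. The loops at Pdzd7, Cd82, Nxph4 and Pebp1 departed from the ratio of PETs that shared loops had in common (adjusted p = 3.33e-07, 5.26e-11, 1.7e-36 and 0.00146, exact binomial test with Benjamini-Hochberg). An anchor of the loops at Ago2 and Pdzd7 overlapped a block without signal in either replicate.

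The promoter with the most shared loops was that of Tjp3, a tight junction scaffold gene on chromosome 10 (81273207 to 81291581), with 34. Its neighbour Pip5k1c, a phosphoinositide kinase gene, had 22. Rhbdf2, an inactive rhomboid protease gene on chromosome 11, had 25, Ankrd39 had 23, Gm20219 had 21, Tmem270 had 19 and the netrin gene Ntn5 had 18. The gamma protocadherin genes Pcdhga5, Pcdhga11 and Pcdhga12 completed the 10 genes with the most, with 18, 17 and 17. These are counts of distinct loop pairs within 2.5 kb of a transcription start site, and neighbouring starts shared some of them.

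The clustered protocadherins, cell surface proteins whose promoters bind CTCF and are chosen at random in neurons, stood far above other genes. Of 56 members, 46 (82.1%) had their promoter at an anchor of a shared loop, against 24.7% of other protein-coding genes (odds ratio 14.0, adjusted p = 1.5e-18, two-sided Fisher's exact test with Benjamini-Hochberg over 15 lists). With the loops of replicate 1 alone 56 of 56 members had one against 73.0% of other genes, and with those of replicate 2 alone 92.9% against 48.8%, so the share over that of other genes was 3.32 with shared loops and 1.37 and 1.90 with single replicates. The promoter of Pcdhga12 was joined to an exon of Diaph1 downstream of the cluster over 88.2 kb with 305 and 49 PETs, and that of Pcdhga11 to an intron of Diaph1 over 126 kb with 70 and 20 PETs. The Pcdhga12 loop departed toward replicate 1 from the ratio of PETs that shared loops had in common (adjusted p = 4.77e-05, exact binomial test with Benjamini-Hochberg). Pcdhac1, a C-type member of the alpha cluster, anchored a 127 kb loop with 70 and 22 PETs. Pcdhgb6 was joined to the promoter of Pcdhgb7 over 10.8 kb with 69 and 34 PETs. The loops of Pcdhga11, Pcdhac1 and Pcdhgb6 lacked a motif at an anchor in both replicates. A peak lay within 2.5 kb of the start in both replicates in 100% of members, against 70.6% of other genes. A peak with a CTCF motif did so in 25% of members against 21.6% (odds ratio 1.21), so the excess of loops was not matched by motif peaks. A motif was called in only 26.5% and 25.1% of all peaks found in both replicates, so a missing call does not show that CTCF is absent. Members of a cluster share anchors and are not independent of each other.

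Genes of sensory receptors showed the opposite. Of 1134 olfactory receptor genes, which are silent outside sensory neurons, 10 (0.882%) were at a shared loop against 26.2% of other genes (odds ratio 0.0251, adjusted p = 4.46e-125, Fisher's exact test with Benjamini-Hochberg). Olfr71, the receptor gene with the strongest loop, was joined to the promoter of Npr2 over 82.5 kb with 23 and 10 PETs. Olfr94 anchored a 379 kb loop with 20 and 5 PETs, Olfr156 a 60.1 kb loop with 15 and 4, and Olfr70 a 32.3 kb loop with 13 and 3. None of 328 vomeronasal receptor genes was at a shared loop (adjusted p = 8.97e-41, Fisher's exact test with Benjamini-Hochberg). Few of these genes had a peak of the CTCF library, with or without a motif, within 2.5 kb of the start in both replicates: 6.08% of olfactory and 2.74% of vomeronasal receptor genes, against 74.2% and 71.7% of other genes. A peak with a CTCF motif lay there in 2.38% and 0.610%, against 22.6% and 21.9% of other genes. Among genes with a peak there, with or without a motif, the olfactory receptors were still below the others (9 of 69, adjusted p = 0.000778), and 0 of 9 vomeronasal receptors had a shared loop against 34.2% of other genes (p = 0.0328, adjusted p = 0.164, Fisher's exact test). With the loops of a single replicate, 143 and 74 olfactory receptors (12.6% and 6.53%, against 76.3% and 51.2% of other genes) and 20 and 8 vomeronasal receptors had a loop.

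Pluripotency genes were more often at shared loops than other genes, with 16 of 37 members (43.2%, odds ratio 2.31, adjusted p = 0.0394, Fisher's exact test with Benjamini-Hochberg). Pou5f1, the gene of the core pluripotency factor Oct4, was joined to a site upstream over 10.8 kb with 46 and 9 PETs and convergent motifs. Fgf4, the growth factor that drives exit from the naive state, anchored a 41.7 kb loop with 34 and 8 PETs, Tdgf1 a 50 kb loop with 21 and 7, and Lefty2 an 11.8 kb loop with 19 and 4. Ribosomal protein genes (29 of 76, 38.2%, odds ratio 1.87, adjusted p = 0.0394) and trophoblast genes (6 of 10, 60%, odds ratio 4.54, adjusted p = 0.0479) also passed the same exact test. Rpl14 anchored a convergent 69.0 kb loop with 140 and 53 PETs, Rpl29 a 48.4 kb loop with 35 and 7, Rplp0 a 12 kb loop with 29 and 9, and Rpl24 a 13.6 kb loop with 24 and 6. Among trophoblast genes, Tfap2c (27 and 4 PETs), Krt8 (19 and 3), Cdx2 (13 and 7) and Ascl2 (12 and 3) had shared loops, while Elf5, Gata3, Hand1 and Krt18 had none. Among genes with a peak at the start in both replicates, the shares were 44.1% for pluripotency, 40% for ribosomal proteins and 60% for trophoblast, against 34.1%, 34.1% and 34.2% of other genes, and the calls ended (adjusted p = 0.428, 0.428 and 0.304, exact test). They also ended with starts within 1 kb (27.0%, 31.6% and 30% against 20.3% of other genes, adjusted p = 0.471, 0.08 and 0.544, exact test), those of pluripotency and trophoblast with starts within 5 kb (adjusted p = 0.0891 and 0.127, exact test), and that of ribosomal proteins with loops over 20 kb (adjusted p = 0.16, exact test). With the loops of replicate 1 alone, all 10 trophoblast genes had a loop against 73.0% of other genes, where 10 genes cannot pass (adjusted p = 0.118, exact test). With loops of at least 10 PETs in both replicates, 1 of 37, 1 of 76 and 0 of 10 members had a shared loop against 3.62%, 3.63% and 3.62% of other genes, too few to show a direction (p = 1, 0.529 and 1, exact test).

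Among the lists that did not pass, Hox genes, which pattern the body axis, had 16 of 39 members at shared loops (41.0%, adjusted p = 0.0543, Fisher's exact test with Benjamini-Hochberg). Hoxc10 anchored a convergent 211 kb loop with 97 and 23 PETs, Hoxc8 a 191 kb loop with 121 and 18, and Hoxb9 a 9.46 kb loop with 22 and 4. The Hoxc8 loop departed toward replicate 1 from the ratio of PETs that shared loops had in common (adjusted p = 0.0319, exact binomial test with Benjamini-Hochberg). Hoxc5 was counted at the anchor of Hoxc10 only because its annotated start (102967443) lies within Hoxc10 (102966796 to 102971893). The Hoxc5 entry runs to 103017429, past Hoxc8. With loops of at least 10 PETs the Hox list passed, with 5 of 39 members (adjusted p = 0.0478, exact test), as it did with the loops of replicate 1 alone (39 of 39, adjusted p = 1.8e-05) or of replicate 2 alone (30 of 39, adjusted p = 0.0017). It also passed with starts within 5 kb (24 of 39, 61.5% against 30.2%, adjusted p = 0.000243, exact test) and without loops in blocks without signal (adjusted p = 0.0483, exact test). It did not pass among genes with a peak at the start (42.9% against 34.1%, adjusted p = 0.428, exact test), over 20 kb (adjusted p = 0.615, exact test) or within 1 kb (adjusted p = 0.471, exact test). Imprinted genes had 17 of 42 members (40.5%, adjusted p = 0.0562, exact test), among them Cdkn1c and Phlda2 with the loops above. H19, the maternally expressed RNA gene of the Igf2 domain, anchored a 93.6 kb loop to an exon of Lsp1 with 40 and 10 PETs, and the potassium channel gene Kcnk9 a convergent 475 kb loop into an intron of Trappc9 with 37 and 16. The imprinted list passed when only loops over 20 kb were counted (adjusted p = 0.0233, exact test), while with the loops of replicate 2 alone it was at 47.6% against 48.9% of other genes (adjusted p = 0.941, exact test).

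The genes of CTCF, cohesin and their partners had 8 of 18 members at shared loops (adjusted p = 0.144, Fisher's exact test with Benjamini-Hochberg), the strongest at Cdca5 (46 and 7 PETs), Ctcf (22 and 8), Maz (44 and 3) and Stag1 (15 and 3). Mesoderm and endoderm genes had 7 of 16 (adjusted p = 0.144, exact test), with loops at Eomes (45 and 11 PETs), Foxa2 (19 and 8), Fgf8 (31 and 3) and Tbx6 (15 and 4). Neural genes had 5 of 16 (adjusted p = 0.652, exact test; 13 of 16 and adjusted p = 0.0209 with the loops of replicate 2 alone), with Nes as above, Neurog2 (23 and 18 PETs), Gbx2 (28 and 3) and Tubb3 (14 and 3). Housekeeping genes had 7 of 24 (adjusted p = 0.683, exact test), the strongest at Rplp0 as above, Tubb5 (28 and 10 PETs), Actb (37 and 4) and Eno1 (14 and 3). Fibroblast genes, markers of feeder cells, had 5 of 18 (adjusted p = 0.786, exact test), and Col1a1, a collagen gene, anchored a convergent 67.8 kb loop with 151 and 22 PETs. Tagln (10 and 3 PETs), Pdgfra (6 and 4) and Pdgfrb (6 and 4) followed. The Col1a1 loop departed toward replicate 1 from the ratio of PETs that shared loops had in common (adjusted p = 0.0067, exact binomial test with Benjamini-Hochberg). Of 11 genes of the primed or formative epiblast, only Dnmt3b, a DNA methyltransferase gene, had a shared loop, with 6 and 3 PETs (adjusted p = 0.39, exact test). None of 10 genes of the X inactivation centre and X repeats had a promoter at a shared loop (adjusted p = 0.182, exact test). With the loops of replicate 1 alone, 10 of the 11 epiblast genes and 9 of the 10 genes of the X list had a loop, against 73.0% of other genes (adjusted p = 0.33 for both, exact test), and with those of replicate 2 alone 2 and 3 did, against 48.9% of other genes. A loop at a promoter is a contact and not a measure of expression.

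**Figure D2:**
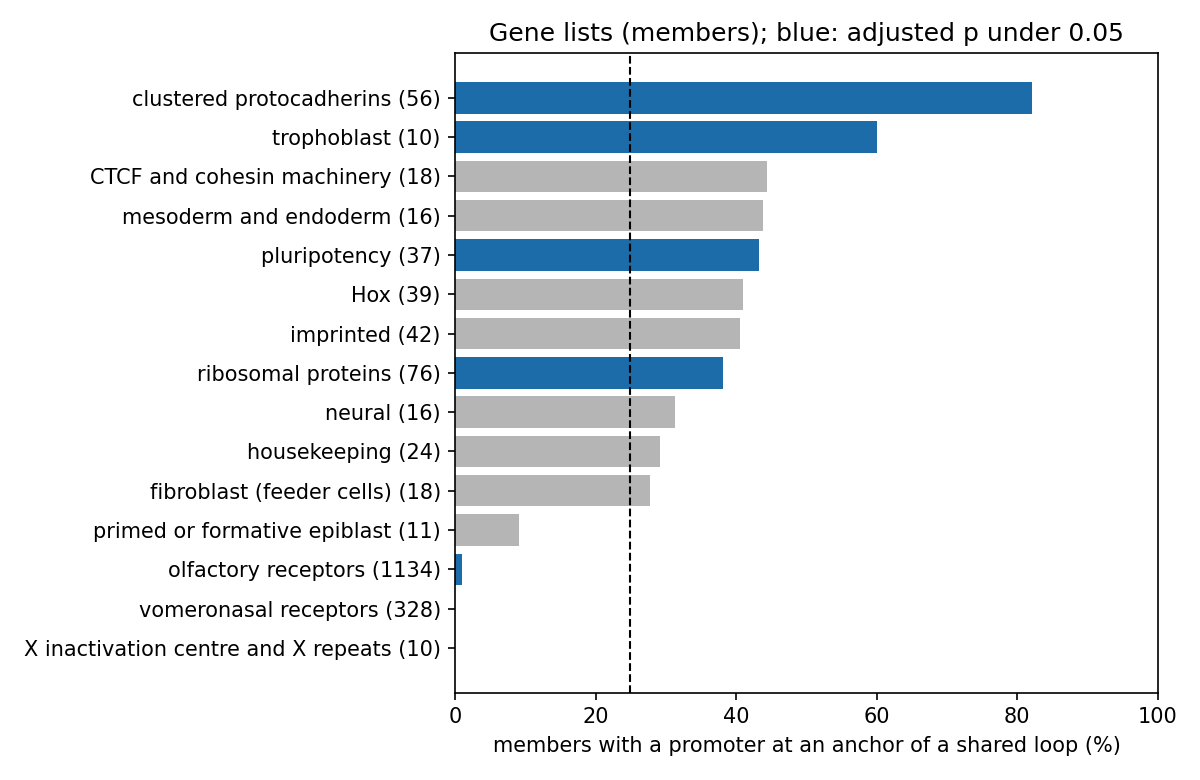
Percent of the members of each gene list with a promoter at an anchor of a loop found in both replicates, with the number of members in brackets and the dashed line at the 24.8% of all protein-coding genes. Blue marks an adjusted p under 0.05, which also holds for the vomeronasal receptors at 0 of 328; the clustered protocadherins reach 82.1%.

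Of 25 loci chosen beforehand, 22 had a shared loop within 250 kb of the named genes. The clustered protocadherin locus had the highest count, with 170 shared pairs among 971 and 272 loops. Its window was 1412 kb long, against 505 kb at Pou5f1, and the counts were not divided by window length. Near Prdm14, a regulator of naive pluripotency, the strongest shared loop was convergent, spanned 83.2 kb and had 141 and 45 PETs. The alpha globin locus, whose genes are expressed in erythroid cells, had a convergent 139 kb loop with 136 and 29 PETs among 52 shared pairs. Nanog had 45 shared pairs, the strongest a convergent 48.4 kb loop with 55 and 11 PETs, and Pou5f1 had 68, the strongest over 27.3 kb with 63 and 26. Near Sox2, a loop from an intron of Sox2ot spanned 120 kb with 29 and 5 PETs. The Klf4, Esrrb and Zfp42 loci had 2, 6 and 3 shared pairs, the strongest with 4 and 3 PETs at Klf4, 14 and 6 at Esrrb and 8 and 5 at Zfp42.

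In windows with 250 kb on each side, there were 67 shared loops at Hoxc, 27 at Hoxb, 5 at Hoxa and 3 at Hoxd. With 500 kb the numbers were 118, 57, 5 and 7, and with at least 10 PETs 4, 0, 1 and 0, so only Hoxc kept its place. At Hoxa, the loop between the annotated starts of Hoxa3 and Hoxa6 and that of Hoxa7 spanned 9.91 kb with 12 and 14 PETs. The anchor at Hoxa3 and Hoxa6 was centred in an intron of the Hoxa3 entry. The strongest at Hoxb lay within Igf2bp1 (23 and 4 PETs), and Hoxd had a convergent 248 kb loop with 21 and 3. Among imprinted loci, the promoters of Peg3 and Usp29 were joined to an intron of Zim2 over 68.2 kb with 52 and 7 PETs, the strongest loop of the window around H19 and Igf2 lay between Ifitm10 and Syt8 with 58 and 10 PETs, and the window around Dlk1 and Meg3 had a single shared loop with 5 and 3 PETs. On the X chromosome, a convergent 181 kb loop near Xist and Tsix had 16 and 6 PETs, and a convergent 19.2 kb loop into Firre had 7 and 3. The window around Ctcf had 55 shared pairs, the strongest at Hsd11b2 with 100 and 20 PETs, Rad21 had 3, the strongest a convergent 133 kb loop with 20 and 8 PETs, and the window from Shh to Lmbr1 had 3, the strongest with 14 and 4. Myc, the interval from Epha4 to Pax3 and the beta globin cluster had loops in each replicate and none in both. With loops of at least 10 PETs in both replicates, 10 loci had a shared loop, and with windows of 500 kb 23 had one.

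Most loops had a peak of the CTCF library at an anchor, and neither anchor held one in 7.31% and 14.3%. Peaks were called without input, and 19.1% and 22.2% of them held a CTCF motif, against 5% and 4.89% of control windows. The median span was 78.6 and 104 kb, a mean of 91.3 ± 17.9 kb (SD, n = 2). Both anchors held a peak of the same replicate in 60.3% and 49.6% of loops, against 8.30% and 3.91% for loops moved along the chromosome, a mean of 54.9% ± 7.59 (SD, n = 2). Loops and peaks came from reads of the same library, so this excess is not independent support for CTCF binding at anchors. A protein-coding start lay within 2.5 kb of an anchor in 30.7% and 28.0% of loops, against 13.9% and 13.2% after moving, a mean of 29.3% ± 1.92 (SD, n = 2). Of the loops of replicate 1, 7.79% were found in replicate 2, and 34.3% of those of replicate 2 were found in replicate 1, where moved loops gave 0.242% and 1.01%. The share found in the other replicate rose from 2.32% and 26.2% at 3 PETs to 39.5% and 87.0% at 10 to 19 PETs and 98.7% and 100% at 50 or more. It fell with span, from 11.4% and 56.4% up to 20 kb to 0.103% and 0.238% over 3 Mb. Requiring 50% of both anchors to overlap reduced the shared percent to 3.03% and 12.9%, and widening anchors by 5 kb raised it to 26.6% and 53.2%. Thinning the PETs of replicate 1 by the ratio of the PET totals changed it to 37.8% and 14.4%. Loops left under 3 PETs were then dropped, so thinned replicate 1 had fewer loop PETs than replicate 2 and the depths were not equal.

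CTCF motifs at loop ends faced each other more often than independent orientations would give. Among loops with a motif in a peak at both anchors, 39.9% (95% Wilson interval 39.6 to 40.3) of 62361 in replicate 1 and 48.0% (47.2 to 48.8) of 16098 in replicate 2 were convergent, against 25% for independent orientations (exact binomial test, two-sided, p under 1e-300 in both). Tandem pairs made up 44.98% and 40.3%, and divergent pairs 15.1% and 11.7%. Loops with a motif at both anchors were 15.7% and 17.4% of all loops, so the orientation of the rest is not known. The convergent share depended on span: it was 23.9% and 25.6% up to 20 kb, 46.3% and 58.0% from 100 to 500 kb, 55.4% and 61.4% from 500 to 1000 kb, and 26.9% and 24.4% over 3 Mb, where the intervals of 23.3 to 30.8 and 18.96 to 30.8 held 25%. With 20 to 49 PETs it was 53.9% and 73.6%. Loops of 1 library share anchors, so the intervals cover counting error only and the test compares loops, not samples.

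**Figure D3:**
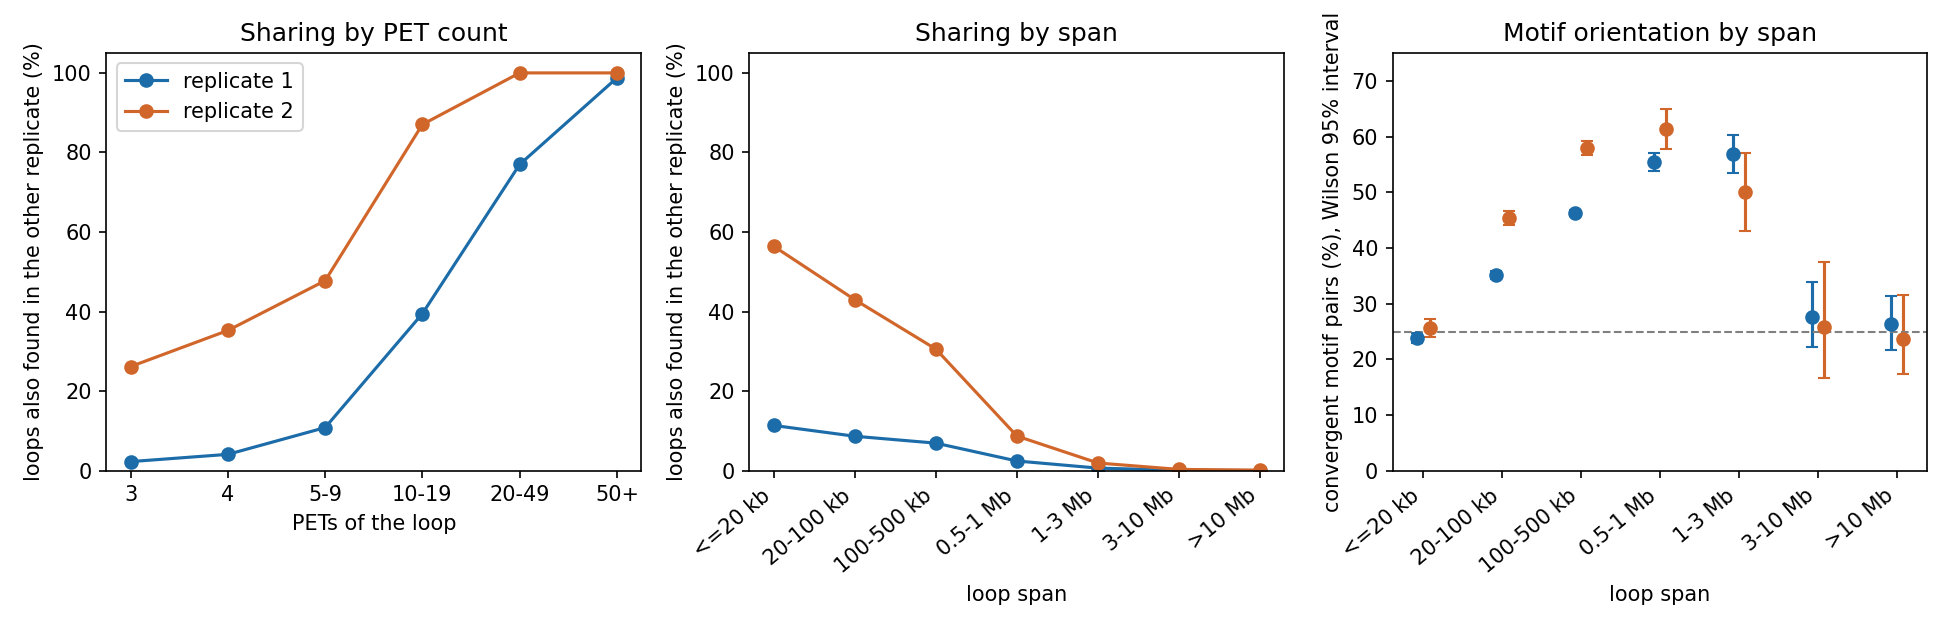
Percent of loops also found in the other replicate by PETs per loop (left) and by span (middle), and percent of convergent motif pairs by span with 95% Wilson intervals (right), for replicate 1 in blue and replicate 2 in orange. Sharing reaches 98.7% and 100% at 50 or more PETs, and the convergent share is near the dashed line at 25% up to 20 kb and over 3 Mb.

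Peaks of the CTCF libraries were shared more widely than loops. Of the peaks of replicate 1, 64.1% overlapped a peak of replicate 2, and 85.5% of those of replicate 2 overlapped a peak of replicate 1, against 10.2% and 13.3% after moving. The peaks with the smallest q (the top decile of each list, 27819 and 21083 peaks) were shared in 99.996% and 100%, and those with the largest q in 26.3% and 59.6%. Peaks found in both replicates held a CTCF motif in 26.5% and 25.1%, and peaks found in 1 replicate in 5.80% and 4.99%, near the 5% and 4.89% of control windows. On chromosomes not used to build the motif, 75.7% and 81.4% of the top decile of peaks held a motif. The signal in 249112 bins of 10 kb had a Pearson r of 0.989 and a Spearman correlation of 0.987 between replicates, which is across bins that are not independent replicates.

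Few shared loops departed detectably from a common ratio of PETs between replicates. There were 28170 mutual best pairs of loops with a median span of 44.4 kb and a ratio of PET totals of 2.92, and their counts had a Spearman correlation of 0.458 across loops, which are not independent replicates. Pairs needed at least 3 PETs in each replicate, and the ratio over all nuclear loop PETs was 5.15. Of these pairs, 440 departed from the shared ratio (exact binomial test, two-sided, with Benjamini-Hochberg at 0.05), 371 toward replicate 1 and 69 toward replicate 2. When only the 19261 pairs with at least 10 PETs over both replicates were tested, against their own ratio, 466 departed, 263 and 203 in the 2 directions. The split was 1385 and 1561 among the 2946 of 28170 pairs with an unadjusted p under 0.05 (exact binomial test). The balance of directions thus changed with the pairs tested and the threshold. The test sets the difference between 2 libraries against the counting error of PETs alone, so its p-values do not measure the spread between biological replicates. The largest ratios toward replicate 1 were within Sfi1, a centriole gene, on chromosome 11 (3131457 to 3180633; 718 and 8 PETs, 30.7 times the shared ratio, adjusted p = 3.42e-74, exact binomial test), between Gna11 and Aes (175 and 5 PETs), within the transcription factor gene Nfic (98 and 3), between a site beside Aes and the promoter of Tle6 (97 and 3) and at Apoe and Tomm40 (86 and 3). An anchor of the loops at Tle6 and Myh9 overlapped a block without signal in either replicate. The largest toward replicate 2 joined Myh9, a nonmuscle myosin gene, to Txn2 (3 and 13 PETs, 0.0790 times the shared ratio, adjusted p = 0.00101, exact binomial test), lay at Shroom3 (3 and 13), joined Cfap100 to Aldh1l1 (3 and 13), and lay within Plxdc1 (3 and 11) and at Hnf1aos1 (3 and 11). In pairs that departed toward replicate 1, the anchors were 4.21 times as wide in replicate 1 as in replicate 2 (median, 6286.5 and 1413 bp), against 1.44 times in pairs that did not depart. When 50% of both anchors had to overlap, 9 of 11997 pairs departed. Only 1 of the 371 pairs toward replicate 1 and 28 of the 69 toward replicate 2 were still paired in that setting. Of pairs that did not depart, 41.2% were, so most of the 440 could not be tested again. Of the 10 named loops, 3 were still paired and did not depart, and the other 7 could not be tested. In simulated data, 4-fold changes were found in 5.5% of 200 loops of any depth and in 79.5% of 200 loops of at least 50 PETs, and 2-fold changes in 0% and 6%. The simulation drew counts from the binomial model of the test, without the PET minimum in each replicate or the pairing by anchors.

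The sex chromosomes, each present once in male cells, had less signal than any autosome. The X chromosome had 0.226 and 0.241 times the signal per base of the median autosome, a mean of 0.234 ± 0.0110 (SD, n = 2), below the lowest autosome, chromosome 3, at 0.661 ± 0.0188. In bins without a peak and against autosomal bins of the same GC content, X was at 0.5 and 0.505, a comparison added after the data were examined. Chromosome 11, rich in genes, was highest at 1.59 and 1.56, and at 1.101 and 1.08 in the comparison at the same GC content, where chromosome 19 was higher at 1.12 and 1.14. Chromosome 11 also had the most loops per Mb, 329 and 76.2, against 20.9 and 5.68 on X. The Y chromosome was at 0.00189 and 0.00228, with 2 loops in each replicate and none shared, and 95.7% of its length lay in blocks of at least 10 kb with no signal in either replicate. Outside those blocks, Y was at 0.0474 (mean, n = 2).

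**Figure D4:**
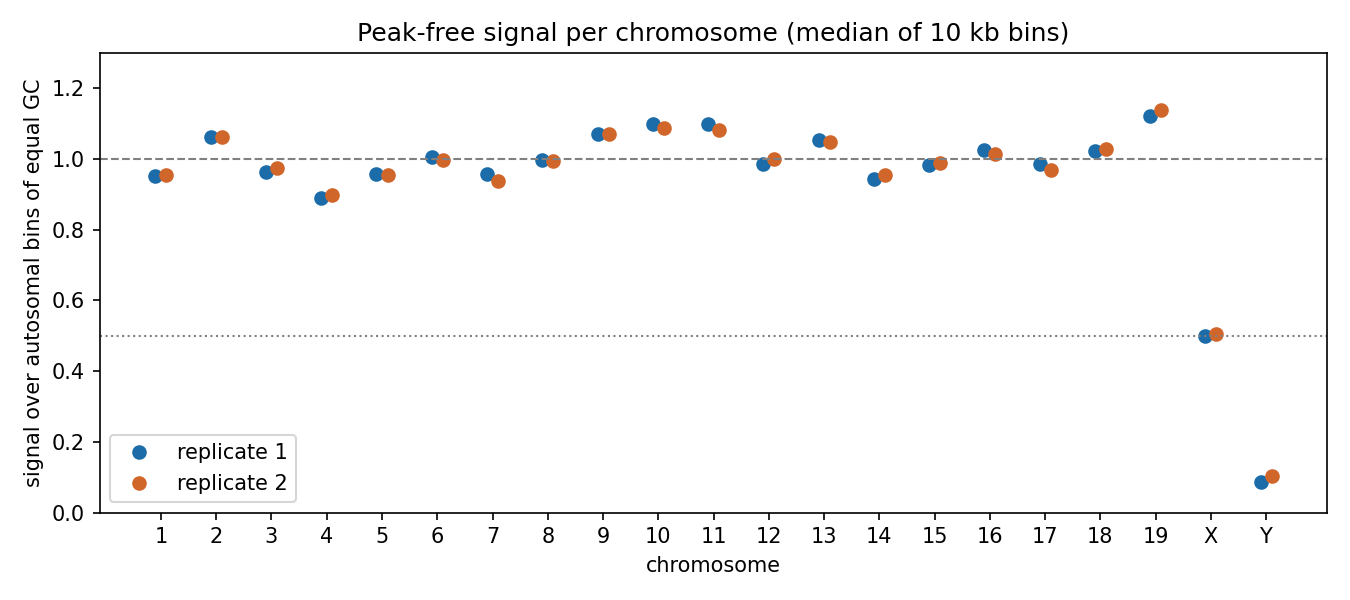
Median signal of 10 kb bins without a peak on each chromosome over that of autosomal bins of equal GC content, for replicate 1 in blue and replicate 2 in orange, with lines at 1 and 0.5. X lies at 0.5 and 0.505, autosomes lie between 0.889 and 1.14, and Y lies at 0.0872 and 0.104 over the 331 bins that remain.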

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

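The test of CTCF enrichment, the test of block edges on Y and all 3 tests of loops over 3 Mb were chosen only after the result was seen. The mitochondrial loops were singled out because they are a strong signal in data outside the comparisons. In replicate 1, a single loop joined positions 1 to 7004 and 10407 to 16299 of the 16299 bp mitochondrial genome with 94739 PETs, or 4.55% of all loop PETs. In replicate 2, the corresponding loop joined positions 1 to 6992 and 10407 to 16299 with 39715 PETs, or 9.32%.

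Replicate 1 listed 4.27 times as many loops as replicate 2, with 2.33 times the signal. Bins with a shared peak held 50.4% of the signal of replicate 2, against 49.1% in replicate 1. This cannot decide on a weaker enrichment of CTCF fragments in replicate 2, since the peaks also had to be called in that replicate. Only 26.5% of these peaks held a CTCF motif. Sequencing depth may account for the number: thinning the PETs of replicate 1 by the ratio of the signal gave 1.11 times the loops of replicate 2 (mean of 20 draws). It left 6504 loops of at least 10 PETs on average, against 2613 in replicate 2, so the higher PETs per loop stay open, and thinning keeps the anchors as they were called in replicate 1. No biological explanation was tested, since there is 1 group.

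Signal on the Y chromosome was close to absent, although the cells are male. Regions left out of the signal track before deposit are a candidate explanation for the blocks without signal, since 20% of 55 such blocks on Y (Wilson 95% interval 11.6 to 32.4) had an edge on a multiple of 100 bp, against 1.99% by chance, and these held 98.7% of the length of the 55. Outside the blocks, Y was still at 0.0474 of the median autosome, and the signal pooled over the bodies of 4 Y genes was 0.221 and 0.239 of that over their X homologues, which met the bound of under 0.25 set for a loss of Y in most cells before the ratio was seen. The demand that each gene also meet it was added after the values were seen, because the ratios ran from 0.0514 at Kdm5d to 0.744 at Uty and the X homologues Kdm5c and Eif2s3x were themselves at 17.0 and 19.9 reads per base in replicate 1, against 2.96 at Kdm6a. Outside peaks, the 4 genes were at 0.348 to 0.657 of the median of 477 X genes. Reads lost to repeats and a loss of Y in most cells therefore cannot be told apart for the part of Y outside the blocks. No biological explanation other than a loss of Y was tested.

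Loops over 3 Mb were almost never found in both replicates. Chance ligation of unlinked fragments is consistent with their motif orientation, since 26.9% (23.3 to 30.8) of 536 pairs in replicate 1 and 24.4% (18.96 to 30.8) of 201 in replicate 2 were convergent, although these were 2.90% and 2.65% of the loops. Both anchors held a peak in 24.99% and 18.3%, above the 8.30% and 3.91% of moved loops of any span, but this was 0.9899 and 0.971 times the share after right anchors were exchanged among these loops, as chance ligation between fragments with peaks would give. Rearrangements of the strain against the reference would be carried by both replicates and are argued against as the source of the whole set, since 0.238% (Wilson 95% interval 0.150 to 0.375) of the 7573 such loops of replicate 2 were found in replicate 1, against 36.7% of loops up to 1 Mb weighted to the same PETs. The 18 loops found in both replicates stay open, since moving the loops gave 0, and no biological explanation other than rearrangements was tested.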

How the results depend on the processing

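Of the alternatives, those that limit loops by span or by regions with signal, genes by peaks, and signal bins by GC content or by blocks without signal were chosen only after the data were seen. Over all 261 comparisons of a value with an alternative, 144 stayed within a tolerance or kept their call, 11 lost the threshold, 7 gained it, 86 moved and 13 changed direction. The tolerance differed by result: 1 SD of the replicates for means, which single replicates meet by construction, the 95% interval for shared percents and the correlation, a factor of 1.5 for counts, and the same side of the threshold for gene lists (89 of 120). A value within it can still differ, and one outside it can be close. The cause was not tested for the values that moved, except that a higher PET minimum leaves fewer loops and a wider or narrower window changes what can be counted. Depth limits what can be matched, since 51.2% and 56.0% of loops had 3 PETs. All alternatives fixed before the data were examined were run.

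Shared peaks of replicate 1 and replicate 2 were 54.4% and 71.8% with 50% overlap, 67.7% and 89.7% with the higher-scoring part of the peaks, and 74.6% and 76.0% with equal numbers of peaks. Shared loops were 9.01% and 47.8% with at least 5 PETs, 8.60% and 84.8% with at least 10 PETs, 26.6% and 53.2% with anchors widened by 5 kb, 3.03% and 12.9% with 50% overlap, 37.8% and 14.4% with replicate 1 thinned, 10.8% and 57.4% with a peak at both anchors, and 8.40% and 39.1% up to 1 Mb. With at least 10 PETs, the mean of the median spans was 51.9 kb, loops with a peak at both anchors 93.4%, convergent pairs 58.4%, loops with a promoter 38.9% and loci with a shared loop 10. The span of shared loops was 43.6 kb. Loops with a peak at both anchors were 42.9% with higher-scoring peaks and 69.4% with anchors widened by 1 kb. Convergent pairs were 52.8% from 100 kb to 1 Mb, and loops with a promoter 20.8% within 1 kb and 40.3% within 5 kb. With single replicates, span ranged from 78.6 to 104 kb, peak support from 49.6% to 60.3%, convergent pairs from 39.9% to 48.0%, loops with a promoter from 28.0% to 30.7%, the X signal from 0.226 to 0.241 and lists past the threshold from 6 to 8.

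The number of gene lists past the threshold was 3 with starts within 1 kb and 2 among genes with a peak. The 13 changes of direction were all in gene lists, as the share of members with a loop over that of other genes, and none passed the threshold in the setting that changed it. With at least 10 PETs, the ratio was 0.746 for pluripotency, 0.363 for ribosomal proteins and 0 for trophoblast and for CTCF and cohesin, from 1, 1, 0 and 0 genes, too few to show a direction. With loops over 20 kb it was 0.912 for housekeeping and 0.684 for mesoderm and endoderm genes, among genes with a peak 0.976 for housekeeping, 0.861 for fibroblast and 0.976 for neural genes, and without loops in blocks without signal 0.863 for housekeeping genes. With single replicates it ranged from 0.372 to 1.25 for the primed epiblast, 0.973 to 1.17 for imprinted genes and 0.613 to 1.23 for the X list. Loops that departed from the ratio of the pairs in each setting numbered 9 with 50% overlap, 2946 with an unadjusted p and 275 over 20 kb. With 50% overlap, only 1 of 371 departing pairs toward replicate 1 and 28 of 69 toward replicate 2 were still paired, so most could not be tested again. The X signal was 0.480 without peaks, 0.252 outside blocks without signal and 0.503 at the same GC content. The correlation of signal was 0.916 in 1 kb bins, 0.998 in 100 kb bins, 0.993 with the larger offset and 0.988 without the highest 1% of bins.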

Other observations

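The loops and blocks described here were examined only after the data were seen. Among the 18 loops over 3 Mb found in both replicates, several were far above the median of 3 PETs per loop. The strongest joined an intron of Gm16302 at 14844388 to 14848190 and an exon of 4930516B21Rik at 119439802 to 119441959 on chromosome 9, a span of 104.6 Mb, with 48 and 23 PETs. On chromosome 17, a site at 33864297 to 33866189 was joined to an intron of Efhb over 19.5 Mb with 47 and 21 PETs. Also on chromosome 17, an anchor at the Phf1 promoter within Kifc5b was joined to an intron of Kifc1, a kinesin gene of the same family, over 6.95 Mb with 21 and 5 PETs, and a second loop from Phf1 to Kifc1 had 7 and 4 PETs. A loop on chromosome 14 over 7.19 Mb had 32 and 15 PETs.

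Blocks of at least 10 kb without signal in both replicates, leaving out those almost wholly of N, numbered 1797 and covered 191.5 Mb. Of this, 87.8 Mb were on Y and 16.6 Mb on X. An edge lay on a multiple of 100 bp in 72.6% of them, against 1.99% by chance. Loops with an anchor in such a block made up 2.55% and 2.502% of the loops, and 4471 and 3587 peaks lay in them. Of the 440 loops that departed from the shared ratio, 18 had an anchor in such a block, among them the loop between Myh9 and Txn2.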
